A study of Acer rubrum with 15 samples.

How the data were processed

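Small RNA from leaves of Acer rubrum 'Autumn Blaze' cuttings was measured in 15 samples, 3 in each of 5 groups taken from the sample labels. Per the labels' protocols, total RNA was extracted with an RNeasy kit, and libraries were made with the Small RNA Sample Pre Kit, PCR and size selection by PAGE. The labels place the plants in an ordinary greenhouse before sampling and give no light level for the day 0 leaves.

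The authors deposited one table for all libraries. Its counts were deposited as raw numbers of reads per small-RNA feature. The TPM values in the same table were computed by the authors as reads scaled to the total of the whole library, per the file headers and the values, with no length term, and were not tested. Trimming, aligner, genome build, databases and the treatment of reads with several matches are not given in the sources used here. The table held 176 hairpin and 167 mature entries with known miRNA names, 76 predicted miRNAs, 7972 predicted siRNAs and entries of other RNA classes. Reads with no named small RNA (exon, intron and intergenic), 67.8% to 86.0% of a library, and predicted siRNAs (2.27% to 3.73%) were left out. No entry carried an animal species prefix (0), but entries named after animal precursors, such as mir-184, were present. Predicted miRNAs were listed with 0 or at least 10 reads, so a 0 there can hide a few reads. Member names within a family came without sequences, so how reads were divided between near-identical names cannot be checked.

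The 243 miRNAs (mature and predicted) were tested singly. Families were sums of mature and hairpin reads whose names carry the same miRNA number, which assumes that a shared number means a shared family. After edgeR's filterByExpr with its default settings, 179 miRNAs (105 known, 74 predicted) and 34 of 35 families were tested, miR530 with 8 reads being left out. Counts were scaled by the trimmed mean of M-values (TMM, factors 0.616 to 1.57) and fitted in edgeR 4.0.16 (quasi-likelihood, R 4.3.3) with 1 mean per group over all 15 libraries. Comparisons were each regime with day 0, the temperature effect at each light level, the light effect at each temperature, their interaction and both averages, 11 in all. A call is a Benjamini-Hochberg adjusted p under 0.05 over the features of a comparison. The biological coefficient of variation was 0.679 for miRNAs and 0.428 for families. Taking all reads of the table as library size in place of TMM moved the median log2 change of all miRNAs by -0.29 (CC), -0.18 (CL), -0.08 (LC) and -0.28 (LL) against Control. The shift was 0.20 for LC against CC, -0.10 for LL against CL, 0.10 for CL against CC, -0.20 for LL against LC, -0.30 for the interaction, 0.05 for temperature and -0.05 for light.

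The comparisons, their tests, a first set of alternatives, the lists and the rule for naming miRNAs were fixed before the data were examined, and further alternatives were added later. Lists were families of phase change (SPL and AP2), MYB targeting, copper response, auxin signalling, leaf and meristem development, nutrients (phosphate and sulfate), resistance genes, small-RNA machinery, cold response in Arabidopsis, and a reproductive-tissue family as an outside list. The 8 lists with at least 2 tested miRNAs were tested with fry on voom values (limma 3.58.1), with adjustment over the 8 lists of a comparison. They were also tested with camera and an estimated correlation, which compares a list with the other miRNAs. Of 88 list tests 45 passed by fry. Named were the 10 largest rises and falls per comparison among called miRNAs with groups that did not overlap and a mean of at least 10 CPM in a group, the 10 smallest adjusted p of the interaction, the families of the lists and the 10 most abundant miRNAs. From these the text names a part, chosen after the values were seen for calls that few alternatives changed, and it adds families outside the lists and miRNAs listed at 0 in a group.

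Precision was checked on simulated data with the mean levels of all 15 libraries and the spread of the fit over the 5 groups. Changes were put into LC and tested against CC, so the data do not carry the levels of these 2 groups. With 20 simulations, 13.2%, 62.3% and 72.3% of miRNAs with true folds of 2, 4 and 8 were called, with 3.0% false calls, and 38.3%, 76.7% and 90.0% of families, with 6.11% false calls. Folds of 2 were therefore often missed in data simulated on these libraries. For comparisons that share the Control libraries, unchanged groups were simulated. Alternatives were relative-log-expression size factors, library size only, all reads of the table as library size, no and stricter filters, DESeq2 1.42.0, the replicate number as a block, only the groups compared, a fold of at least 2, hairpin reads added or left out, predicted miRNAs left out, the most abundant member for a family, and each library left out in turn. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Intervals and SE cover the spread between libraries, and PCR reads without molecular identifiers are not independent molecules.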

Results

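Small RNA was sequenced from leaves of cuttings of the red maple Acer rubrum 'Autumn Blaze', a tree grown for its autumn leaf colour, in a study of leaf colour change under different light and temperature. The design crossed 100% and 40% light with a warm regime of 30 °C by day and 20 °C by night and a cool regime of 15 °C by day and 5 °C by night. Leaves were taken after 14 days under full light and warm (CC), 40% light and warm (CL), full light and cool (LC) and 40% light and cool (LL), and on day 0 before the regimes began (Control). Each of the 5 groups held 3 libraries, 15 in all. The libraries totalled 15652847 to 20822592 counted reads, of which 1780320 to 4045539 carried the name of a miRNA. The labels call the samples biological replicates, but nothing in them says that they came from separate plants, so p-values measure the spread between these samples, whatever its source. Levels are in CPM of the miRNA reads after TMM scaling, given as mean ± SD over n = 3 libraries, and log2 changes are given ± SE. The SE was derived from the test, as the absolute log2 change over the square root of its F statistic, and is no separate estimate. Adjusted p-values of miRNAs and of families (the summed reads of all entries with the same miRNA number) come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Those of lists of families come from limma's fry, which tests whether the members of a list moved, on balance, one way and does not compare the list with other miRNAs. Those given with an estimated correlation come from limma's camera, which asks instead whether a list moved more than the other miRNAs. A list can therefore pass by fry and not by camera without its own move being lost.

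The most abundant miRNA was a predicted one, novel_mir73, with 30.3% of all miRNA reads. It was followed by miR166a-3p (18.3%), which regulates HD-ZIP transcription factors of leaf polarity, and miR398b (14.5%), a regulator of copper/zinc superoxide dismutases. Next came miR858b (10.97%), a regulator of MYB factors of flavonoid synthesis. miR159a_1 (5.65%), novel_mir54 (2.11%), novel_mir21 (1.66%), miR482d-3p_2 (1.41%), novel_mir53 (1.29%) and miR167f-5p (1.26%) completed the 10 most abundant. In each library its own 10 most abundant miRNAs together held 81.7% to 92.7% of the miRNA reads. Across miRNAs, which are not independent replicates, log2 levels of 2 libraries of the same group correlated with a median r of 0.905 (0.818 to 0.952, 15 pairs). For 2 libraries of different groups the median was 0.807 (0.718 to 0.924, 90 pairs). The first principal component held 28.6% of the variance and placed the Control and LL libraries (9.85 to 15.0) on the opposite side from the CC and CL libraries (-14.9 to -8.51), with LC libraries between -7.31 and 4.82. The second component (17.3%) set the LC libraries (-19.6 to -15.7) apart from the other 12, which lay between -2.96 and 8.23. The third (13.1%) cut across the regimes. It set CC replicates 1 and 3, LC replicate 2 and LL replicate 3 (9.33 to 15.0) apart from the remaining libraries (-10.2 to 0.334).

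The comparison of LC with CC asked how leaf miRNAs differed between the cool and the warm regime under full light. Families tied to phosphate and copper supply were higher in the cool regime. Between regimes, words such as rose, fell, raised and lowered give differences on day 14, not changes over time. miR827, a regulator of phosphate-handling SPX-domain proteins, rose 17.4-fold, from 3.88 ± 0.54 to 68.3 ± 18.2 CPM (log2 change 4.12 ± 0.24, adjusted p = 1.54e-08). miR399, which targets a ubiquitin-conjugating enzyme of phosphate uptake, rose 24.7-fold (4.63 ± 0.56, adjusted p = 1.69e-05). The copper families rose as well: miR397, which targets laccases, 5.16-fold (2.37 ± 0.48, adjusted p = 0.00117), and miR398 17.0-fold (4.09 ± 0.96, adjusted p = 0.00344). miR395, a regulator of sulfate assimilation, rose 4.07-fold (adjusted p = 0.000313) and miR2111 8.74-fold (adjusted p = 1.69e-05). Among developmental families, miR156, which represses the SPL factors of phase change, rose 3.36-fold, from 4014 ± 523 to 13478 ± 795 CPM (1.75 ± 0.23, adjusted p = 3.56e-05). miR164, which represses NAC factors of organ boundaries and ageing, was 8.43-fold lower, at 626 ± 348 against 5277 ± 455 CPM (-3.08 ± 0.36, adjusted p = 1.69e-05). miR168, which targets the main ARGONAUTE of the miRNA pathway, rose 4.34-fold (adjusted p = 0.000218), and miR390, which triggers trans-acting siRNAs of the auxin response, 1.92-fold (adjusted p = 0.00239).

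In all, 20 of 34 families passed in LC against CC, 15 higher and 5 lower. The 3 LC libraries lay on one side of the 3 CC libraries in 19 of all 34 (chance 10%), and among the called families they overlapped for miR408, miR170 and miR4995. Calls were also lost for miR170 without CC replicate 1, 2 or 3 or LC replicate 1 (adjusted p up to 0.964, 0.00714 to 0.964 over all alternatives) and for miR4995 without CC replicate 2, LC replicate 1 or LC replicate 3 (adjusted p up to 0.606, 0.00309 to 0.606 over all alternatives). LC replicate 1 stood apart from the other LC libraries, with miR398 at 519750.0 CPM against 53337 and 41864. Without it, the log2 change was 2.04 for miR398, 3.50 for miR399 and 1.73 for miR397, and all 3 calls were kept, while without CC replicate 1 it was 5.20 for miR398. miR408, which targets copper proteins such as plantacyanin, rose 7.17-fold (2.84 ± 0.85, adjusted p = 0.0135). Its call was lost without CC replicate 2 or CC replicate 3 (adjusted p up to 0.0553, 0.000169 to 0.0553 over all alternatives). Its log2 change was 3.59 without CC replicate 1 and 2.04 without LC replicate 1. Of the 20 calls, 8 were lost when 1 of the 6 libraries was left out. Besides miR408, miR170, miR4995 and miR403 these were miR159 (without CC replicate 1, 2 or 3 or LC replicate 1 or 2; adjusted p up to 0.183, 0.00773 to 0.348 over all alternatives), miR166 (without CC replicate 2 or 3 or LC replicate 1; adjusted p up to 0.279, 0.00173 to 0.279 over all alternatives), miR169 (without CC replicate 1 or LC replicate 2; adjusted p up to 0.058, 7.67e-05 to 0.058 over all alternatives) and miR171 (without LC replicate 1; adjusted p up to 0.0789, 8.52e-05 to 0.0789 over all alternatives). The call of miR390 was lost by its most abundant member or without hairpin reads (3.75e-07 to 0.181 over all alternatives). The miR395 call, here and in each other comparison where it passed, was lost when the most abundant member stood in for the sum of the family (adjusted p = 0.171 here, 2.42e-09 to 0.171 over all alternatives). Its reads sat mostly under miR395a_5 in some libraries and under miR395b_3 in others, as in CC replicate 1 (508 and 8 reads) and CC replicate 2 (0 and 489).

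By list, all 4 nutrient families measured rose in LC against CC (4 adjusted over the list alone; adjusted p = 0.0129, and adjusted p = 0.434 with an estimated correlation). So did all 3 copper families (3 adjusted over the list alone; adjusted p = 0.00217, and adjusted p = 0.403 with an estimated correlation). Of the 3 SPL and AP2 phase-change families, miR156 and miR157 rose, the latter not with library size only (0.00255 to 0.27 over all alternatives), and miR172 did not pass over all families (3 adjusted over the list alone; adjusted p = 0.00217, and adjusted p = 0.403 with an estimated correlation). The small-RNA machinery list moved up (1 family higher, 1 lower, 2 adjusted over the list alone; adjusted p = 0.00217, and adjusted p = 0.403 with an estimated correlation), with miR168 higher and miR403, which targets another ARGONAUTE, lower. The miR403 call was lost without CC replicate 3 or LC replicate 1 and with each other scaling and DESeq2 (adjusted p up to 0.189, 0.030 to 0.245 over all alternatives). The lists of MYB-targeting (adjusted p = 0.863), auxin-signalling (0.332), leaf and meristem development (0.193) and cold-responsive families (0.606) did not pass, but on family sums the MYB-targeting list passed (adjusted p = 0.0317), and so did the auxin-signalling list in the other direction (adjusted p = 0.0401). Among single miRNAs, 76 of 179 passed, 33 higher and 43 lower, or 43 (16 higher, 27 lower) when only the LC and CC libraries were fitted. miR172b-5p_4 was near absent in CC (0.727 ± 0.291 CPM) and stood at 35.7 ± 19.4 CPM in LC (5.52 ± 0.87, adjusted p = 0.00040). The miR172 family as a sum differed by 0.70 ± 0.29 (adjusted p = 0.0543). miR396b-3p_2 fell to 12.5 ± 5.46 from 139 ± 39.0 CPM (-3.47 ± 0.36, adjusted p = 1.27e-05), while the miR396 family as a sum differed by 0.30 ± 0.26 (adjusted p = 0.348). The predicted novel_mir10 fell to 369 ± 165.7 from 3112 ± 166.7 CPM (-3.08 ± 0.31, adjusted p = 1.19e-05). novel_mir2 and novel_mir37, at 19.6 ± 2.51 and 23.2 ± 9.53 CPM in CC, were listed at 0 in all 3 LC libraries. novel_mir4 (LC 182 ± 238 CPM) was listed at 0 in all 3 CC libraries, where a 0 can stand for fewer than 10 reads.

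**Figure D1:**
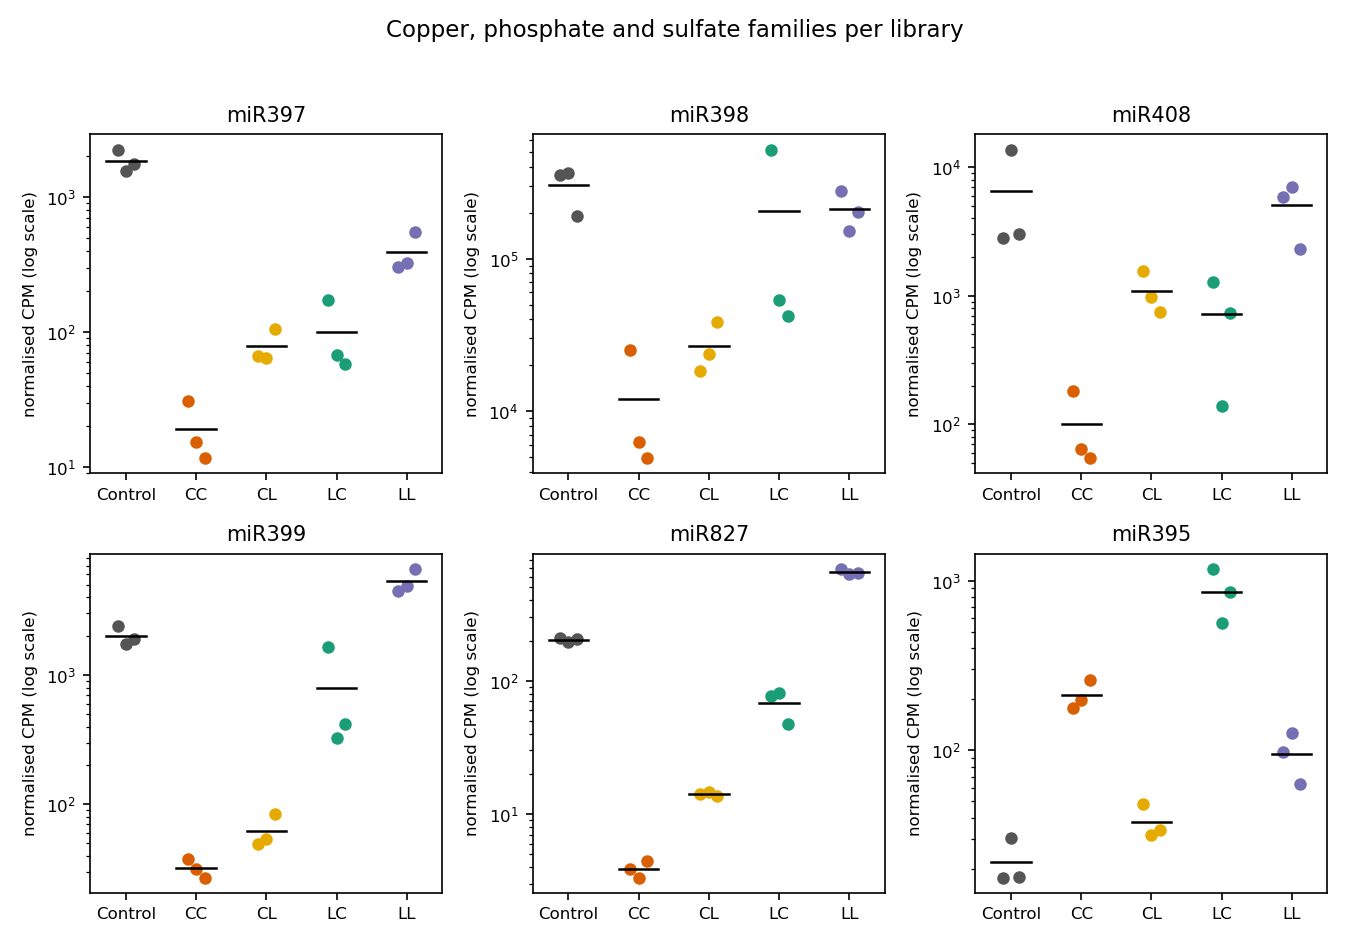
Normalised CPM (log axis) of copper and phosphate miRNA families in each library; points are libraries, coloured by group (Control, CC, CL, LC, LL), and the bar is the mean of 3. For miR827, the 3 LC libraries (47.5 to 80.6 CPM) lie above the 3 CC libraries (3.35 to 4.43 CPM).

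The same question under 40% light was asked by LL against CL. miR827 rose 46.4-fold, from 14.1 ± 0.473 to 654 ± 25.9 CPM (5.54 ± 0.25, adjusted p = 5.45e-10). miR399 rose 84.6-fold, from 62.8 ± 19.3 to 5311 ± 1107 CPM (6.40 ± 0.61, adjusted p = 2.18e-06). The laccase regulator miR397 rose 4.98-fold (2.31 ± 0.47, adjusted p = 0.00234). miR398 rose 7.95-fold (2.99 ± 0.92, adjusted p = 0.0215), a call lost without CL replicate 1, 2 or 3 or LL replicate 1 (adjusted p up to 0.0587, 0.000371 to 0.0587 over all alternatives). For miR408 the log2 difference of 2.21 ± 0.83 did not pass (adjusted p = 0.0503, 0.0068 to 0.167 over all alternatives), though it passed with relative-log-expression size factors, all reads of the table as library size, DESeq2, the replicate block, no hairpin reads or LL replicate 3 left out. The SPL regulators went the other way from full light: miR156 fell by 0.82 and miR157 by 0.79 on the log2 scale (adjusted p = 0.0149 and 0.00942). The miR156 call was lost without CL replicate 2 or 3 or LL replicate 1 or 2 (adjusted p up to 0.0832, 0.00204 to 0.332 over all alternatives). That of miR157 was lost without CL replicate 3 or LL replicate 1 (adjusted p up to 0.0536, 0.00137 to 0.0773 over all alternatives). miR477 held 4 reads over the 3 CL libraries (0.459 ± 0.212 CPM) and 523 over the 3 LL libraries (62.2 ± 30.8 CPM; adjusted p = 0.000618).

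Of 34 families, 12 passed in LL against CL (8 higher, 4 lower), but 4 without CL replicate 3 and 6 without LL replicate 1. The groups did not overlap in 15 of all 34 (chance 10%). The calls of miR827, miR399, miR397 and miR477 were kept under each alternative run. Of the nutrient list, 3 of 4 families and 7 of 10 single members rose (3 families and 7 members adjusted over the list alone; adjusted p = 1.24e-06, and adjusted p = 0.0506 with an estimated correlation). Among these families, the miR395 call was lost when single libraries were left out (adjusted p up to 0.056, 0.000548 to 0.593 over all alternatives). Of the copper list 2 of 3 families and 6 of 7 members rose (3 and 7 adjusted over the list alone; adjusted p = 8.86e-06, and adjusted p = 0.0506 with an estimated correlation). The cold-responsive list moved up (adjusted p = 0.0125, and adjusted p = 0.797 with an estimated correlation), with miR397 and miR169 higher and miR393 lower. miR169 held 27 reads over the 3 CL libraries and 203 over the 3 LL libraries. The calls of miR169 (without CL replicate 3; adjusted p up to 0.062, 0.000371 to 0.23 over all alternatives) and miR393 (without CL replicate 3 or LL replicate 1; adjusted p up to 0.0892, 0.0020 to 0.0892 over all alternatives) were lost when single libraries were left out, and miR169 was at 3.55 without CL replicate 1. The test was also passed by the small-RNA machinery list (adjusted p = 0.0109, and adjusted p = 0.672 with an estimated correlation and 0.365 on family sums) and the leaf and meristem development list (adjusted p = 0.0491, and adjusted p = 0.875 with an estimated correlation and 0.504 on family sums). In the latter the single members had a median log2 change of 0.19 and the family sums one of -0.02. Among single miRNAs, 48 of 179 passed, 31 higher and 17 lower. The split was 25 and 21 with relative-log-expression size factors, 20 and 25 with library size only and 27 and 35 with hairpin reads added, and 31, 28 and 27 passed without CL replicate 1, 2 and 3. miR399b stood at 36.6 ± 10.2 CPM in CL and 2458 ± 604 in LL (6.07 ± 0.73, adjusted p = 0.000168). The laccase regulator miR397a_5 rose from 1.05 ± 0.368 to 22.1 ± 4.58 CPM (4.33 ± 0.40, adjusted p = 1.49e-05).

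Shade in the warm regime was addressed by CL against CC. Under 40% light, miR408 rose 10.9-fold, from 100.2 ± 70.3 to 1092 ± 408.1 CPM (3.44 ± 0.87, adjusted p = 0.00656; 4.19 without CC replicate 1). miR397 rose 4.09-fold (2.03 ± 0.47, adjusted p = 0.00435) and miR827 3.58-fold (1.84 ± 0.23, adjusted p = 0.000104). The differences in miR398 (1.14 ± 0.86, adjusted p = 0.37, 0.0964 to 0.626 over all alternatives) and miR399 (0.96 ± 0.50, adjusted p = 0.175, 0.00471 to 0.509 over all alternatives) did not pass, the latter except with library size only. Nor did those in miR156 (-0.03 ± 0.23, adjusted p = 0.89), miR168 (-0.44 ± 0.33, adjusted p = 0.37) and miR2111 (0.17 ± 0.36, adjusted p = 0.737). The sulfate regulator miR395 was 5.57-fold lower (-2.48 ± 0.36, adjusted p = 0.000192). The NAC regulator miR164 was 4.11-fold lower, at 1283 ± 214 against 5277 ± 455 CPM (-2.04 ± 0.34, adjusted p = 0.000474), and miR169, which targets NF-YA factors of the drought response, 13.5-fold lower (-3.76 ± 0.82, adjusted p = 0.00299). The size for miR169 rests on 27 reads in CL against 382 in CC. miR477 stood at 0.459 ± 0.212 CPM in CL and 69.5 ± 22.5 CPM in CC (adjusted p = 0.000474). miR390 fell by 0.86 and miR403 by 0.83 on the log2 scale (adjusted p = 0.00537 and 0.0026). With library size only, adjusted p = 0.0553 for miR390 (0.000175 to 0.0553 over all alternatives) and 0.375 for miR403 (0.00344 to 0.375 over all alternatives).

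Of 34 families, 12 passed in CL against CC (4 higher, 8 lower; 6 higher and 4 lower with library size only). The groups did not overlap in 15 of all 34 (chance 10%), and among the called families they overlapped for miR4995, whose call was lost without CC replicate 2 or CL replicate 1, 2 or 3 (adjusted p up to 0.641, 0.00363 to 0.641 over all alternatives). The leaf and meristem development list moved down (adjusted p = 0.00369, and adjusted p = 0.408 with an estimated correlation and 0.0604 on family sums), with 4 of 29 members lower (4 adjusted over the list alone) and miR164 the only one of its 5 families to pass. The small-RNA machinery list moved down (adjusted p = 0.000991, and adjusted p = 0.135 with an estimated correlation and 0.0604 on family sums), with 4 of 7 members lower (5 adjusted over the list alone). The copper list moved up (adjusted p = 0.0132, and adjusted p = 0.135 with an estimated correlation), with 2 of 3 families and 2 of 7 members higher (2 and 2 adjusted over the list alone). The MYB-targeting list moved down (adjusted p = 0.0365, and adjusted p = 0.602 with an estimated correlation and 0.16 on family sums), with 2 of 12 members lower (2 adjusted over the list alone). In that list miR319, which in many plants targets TCP factors, fell by 1.33 (adjusted p = 0.0489). This call was lost without CC replicate 1, 2 or 3, CL replicate 2 or CL replicate 3 (adjusted p up to 0.181, 0.00397 to 0.332 over all alternatives), and its log2 change was -2.04 without CL replicate 1. Among single miRNAs, 31 passed, 8 higher and 23 lower, a split of 15 and 14 with relative-log-expression size factors, 9 and 10 with library size only and 17 and 15 with hairpin reads added. The count was 11 without CC replicate 2, 12 without CL replicate 1, 19 without CL replicate 2 or CL replicate 3, and 20 when only the CL and CC libraries were fitted. Most miR164 reads carried the name miR164a_4, which went from 5659.8 ± 348 in CC to 1273 ± 257 CPM in CL (-2.15 ± 0.33, adjusted p = 0.00534).

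Shade in the cool regime was addressed by LL against LC. The phosphate regulators miR827 and miR399 rose 9.56-fold (3.26 ± 0.22, adjusted p = 8.76e-08) and 6.64-fold (2.73 ± 0.51, adjusted p = 0.000566). The copper regulators miR397 and miR408 rose 3.94-fold (1.98 ± 0.46, adjusted p = 0.00259) and 7.04-fold (2.82 ± 0.85, adjusted p = 0.0127). The NAC regulator miR164 rose 3.95-fold, from 626 ± 348 to 2473 ± 329 CPM (1.98 ± 0.34, adjusted p = 0.000309). Without LC replicate 1 these log2 changes were 4.06 for miR399, 2.85 for miR397, 3.82 for miR408 and 2.76 for miR164. The SPL regulator miR156 was 6.04-fold lower, at 2230.3 ± 471.8 against 13478 ± 795 CPM (-2.60 ± 0.24, adjusted p = 1.58e-06), and miR157 2.41-fold lower (adjusted p = 0.000121). miR395 (9.01-fold, adjusted p = 1.17e-05), miR2111 (6.44-fold, adjusted p = 4.83e-05), miR168 (4.87-fold, adjusted p = 0.000109; -1.58 on the log2 scale without LC replicate 1) and miR390 (2.91-fold, adjusted p = 4.83e-05) were also lower, as was miR159, a regulator of GAMYB factors (1.98-fold, adjusted p = 0.000993). miR398 differed by 0.05 ± 0.85 (adjusted p = 0.956), but by 2.35 without LC replicate 1 (adjusted p = 0.00907, 0.00907 to 0.946 over all alternatives).

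Of 34 families, 15 passed in LL against LC (6 higher, 9 lower), and the groups did not overlap in 18 of all 34 (chance 10%). The calls of miR166 and miR171 were lost without LC replicate 1 (log2 change -0.58, adjusted p up to 0.171, 0.00014 to 0.171 over all alternatives, and -0.56, adjusted p up to 0.129, 2.9e-05 to 0.129 over all alternatives). Of the SPL and AP2 phase-change list, 2 of 3 families and 9 of 14 members were lower (2 and 10 adjusted over the list alone; adjusted p = 7.8e-05, and adjusted p = 0.169 with an estimated correlation). The small-RNA machinery list moved down (adjusted p = 6.94e-05, and adjusted p = 0.169 with an estimated correlation), with 4 of 7 members lower (4 adjusted over the list alone). The copper list moved up, with 2 of 3 families and 5 of 7 members higher (2 and 5 adjusted over the list alone; adjusted p = 6.94e-05, and adjusted p = 0.22 with an estimated correlation). In the nutrient list 7 of 10 members were higher (7 adjusted over the list alone; adjusted p = 1.29e-05, and adjusted p = 0.22 with an estimated correlation), 6 of them members of miR399, while of its families miR827 and miR399 rose and miR395 and miR2111 fell. The cold-responsive list moved up (adjusted p = 0.00628, and adjusted p = 0.577 with an estimated correlation), through miR397 and miR408. Among single miRNAs 91 of 179 passed, 57 higher and 34 lower. miR172b-5p_4 fell from 35.7 ± 19.4 CPM to 0.668 ± 0.261 (-5.66 ± 0.89, adjusted p = 0.000312), while the miR172 family sum did not pass (-0.57 ± 0.29, adjusted p = 0.125). miR156a-5p fell from 7259 ± 1184 to 1032 ± 399.6 (-2.81 ± 0.33, adjusted p = 3.61e-05) and miR168a-5p from 30723 ± 10830.0 to 6994 ± 1259 (-2.14 ± 0.28, adjusted p = 8.0e-05). miR396b-3p_2 rose to 231 ± 34.0 (4.20 ± 0.37, adjusted p = 3.74e-06), while the miR396 family sum did not pass (-0.21 ± 0.26, adjusted p = 0.59).

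**Figure D2:**
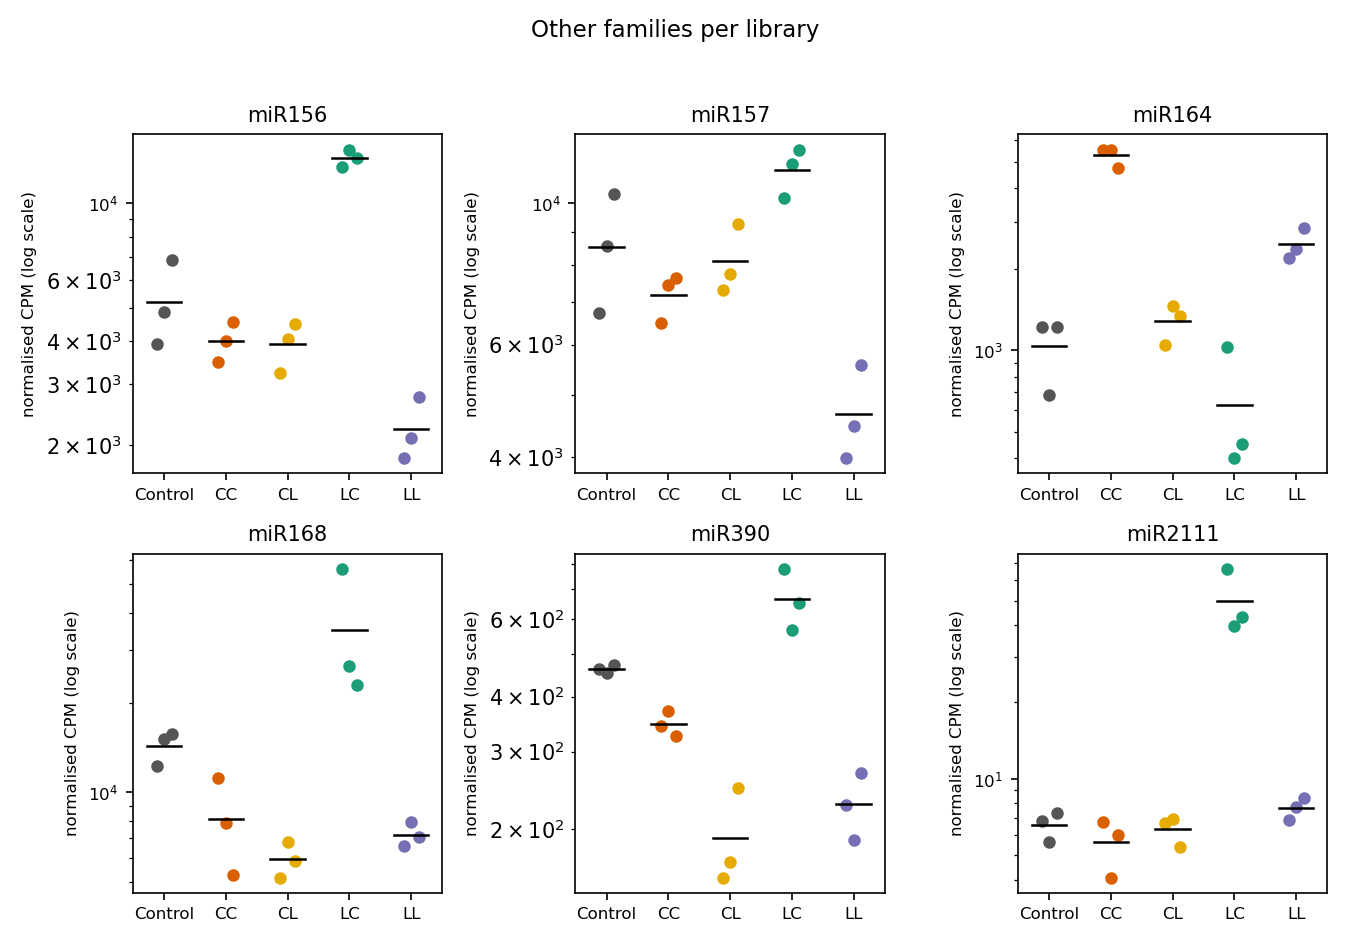
Normalised CPM (log axis) of miR156, miR157, miR164, miR168, miR390 and miR2111 in each library; points are libraries, coloured by group (Control, CC, CL, LC, LL), and the bar is the mean of 3. The 3 LC libraries lie above those of the other groups for miR156, and the 3 CC libraries for miR164.

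The interaction asked whether the temperature effect differed between light levels, and 11 of 34 families passed, 4 with a higher and 7 with a lower effect in 40% light. The effect of the cool regime on miR164 was higher in 40% light by 4.02 ± 0.49 on the log2 scale (adjusted p = 5.29e-05; 4.83 without LC replicate 1). The family was lower in LC than in CC, while its difference of LL from CL (0.95 ± 0.33, adjusted p = 0.0409) lost its call whichever of the 6 libraries was left out (adjusted p up to 0.115, 0.00752 to 0.115 over all alternatives). The effect also differed for miR156 (-2.56 ± 0.33, adjusted p = 5.29e-05), miR157 (-1.44 ± 0.28, adjusted p = 0.00118) and miR2111 (-2.85 ± 0.51, adjusted p = 0.000791). miR168 differed by -1.84 ± 0.47 (adjusted p = 0.0079; -1.14 without LC replicate 1), and miR169 by 5.24 ± 1.10 (adjusted p = 0.00226; 7.25 without LC replicate 1). The size for miR169 is uncertain, since it held 27 reads in CL and 59 in LC, 46 of them in LC replicate 1. miR827 rose in the cool regime at both light levels, by 1.42 ± 0.31 more in 40% light (adjusted p = 0.0030), a difference that did not pass with library size only (adjusted p = 0.0588, 0.0025 to 0.0588 over all alternatives). The differences of miR858 (-1.73 ± 0.53, adjusted p = 0.0252), miR393 (-0.98 ± 0.33, adjusted p = 0.0398) and miR171 (-0.92 ± 0.33, adjusted p = 0.0446) were lost when single libraries were left out. That of miR858 was lost without CC replicate 2 or 3, CL replicate 3 or LC replicate 1 (adjusted p up to 0.0732, 0.00249 to 0.0732 over all alternatives). That of miR393 was lost without CC replicate 2 or 3, CL replicate 3, LC replicate 1 or 3 or LL replicate 1 (adjusted p up to 0.178, 0.00412 to 0.178 over all alternatives), and that of miR171 without CC replicate 1, 2 or 3, CL replicate 3, LC replicate 1 or LL replicate 1 or 2 (adjusted p up to 0.429, 0.00835 to 0.429 over all alternatives). miR477 also passed (adjusted p = 0.000146), but with 4 reads in CL and 50 in LC, 43 of them in LC replicate 1, no size is given.

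miR399 did not pass as a difference between light levels (1.77 ± 0.69, adjusted p = 0.0594), but did without LC replicate 1 (3.13, adjusted p = 4.92e-05, 4.92e-05 to 0.132 over all alternatives) and with library size only (adjusted p = 0.00105), and none of the 3 copper families passed. Tested by its most abundant member in place of the sum, 7 families passed (4 higher, 3 lower). The SPL and AP2 phase-change list moved down (adjusted p = 0.0125, and adjusted p = 0.57 with an estimated correlation), with 2 of 3 families and 7 of 14 members lower (2 and 8 adjusted over the list alone). The nutrient list moved up (adjusted p = 0.0065, and adjusted p = 0.932 with an estimated correlation and 0.792 on family sums in the other direction), with 3 of 10 members higher (3 adjusted over the list alone). Of its families miR827 was higher and miR2111 lower. In the leaf and meristem development list fry found an upward move (adjusted p = 0.0214, and adjusted p = 0.932 with an estimated correlation and 0.26 on family sums), with 5 of 29 members higher (5 adjusted over the list alone). The median of its members was -0.42 and that of its families -0.65. Among single miRNAs 62 passed, 45 higher and 17 lower, a split of 33 and 22 with library size only, 35 and 25 with all reads of the table as library size and 40 and 28 with hairpin reads added. By adjusted p these were led by novel_mir2, which was listed at 0 in LC, miR164a_4 (4.37 ± 0.46, adjusted p = 5.63e-05) and miR396b-3p_2 (4.43 ± 0.48, adjusted p = 5.63e-05). The miR396 family sum did not pass (-0.65 ± 0.37, adjusted p = 0.192).

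**Figure D3:**
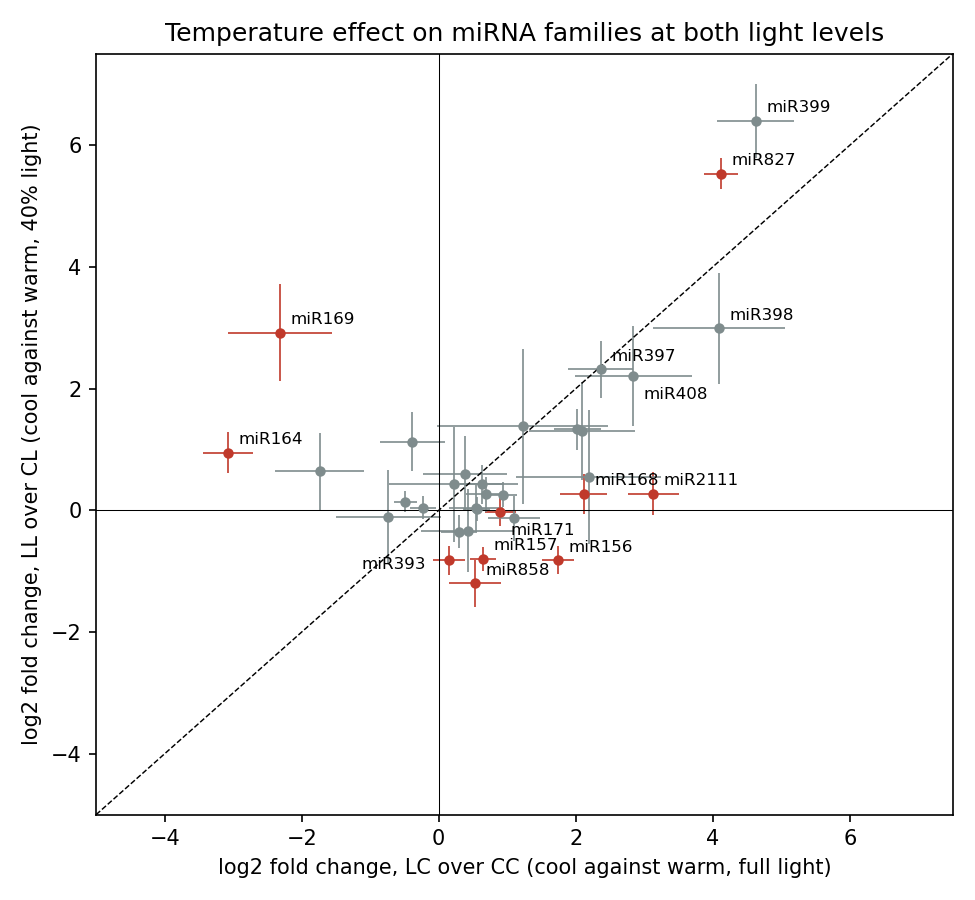
Log2 change of each miRNA family from the warm to the cool regime in full light (x axis, LC over CC) and in 40% light (y axis, LL over CL), each point a family with bars of 1 SE. Red points passed the interaction test, the dashed line marks equal effects, and miR477 is left out; miR827 and miR399 lie high on both axes, while miR164 (-3.08 and 0.95) and miR156 (1.75 and -0.82) lie on opposite sides of 0.

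Averaged over light, miR827 was 28.4-fold (4.83 ± 0.17, adjusted p = 3.35e-11) and miR399 45.7-fold (5.52 ± 0.41, adjusted p = 1.38e-07) higher in the cool than in the warm regime. So were miR397 5.07-fold, miR408 5.76-fold and miR398 11.6-fold (adjusted p = 0.000111, 0.00366 and 0.000842; miR398 at 2.63 on the log2 scale without LC replicate 1). Against day 0, the log2 changes of these 3 were -4.22, -3.18 and -0.56 in LC and -2.24, -0.37 and -0.52 in LL. They were -6.59, -6.02 and -4.65 in CC and -4.56, -2.58 and -3.51 in CL. The copper families thus lay further below day 0 in the warm groups and not above it in the cool ones. The temperature effect passed for 13 families (12 higher, 1 lower, the latter miR164; 9 and 2 with library size only) and 69 miRNAs (34 higher, 35 lower). All 3 copper families rose (adjusted p = 5.83e-06, and adjusted p = 0.102 with an estimated correlation; 3 adjusted over the list alone). All 4 nutrient families rose (adjusted p = 5.39e-06, and adjusted p = 0.108 with an estimated correlation; 4 adjusted over the list alone), miR2111 in full light but not in 40% light (0.28 ± 0.36, adjusted p = 0.62). The small-RNA machinery list moved up (adjusted p = 0.000237, and adjusted p = 0.313 with an estimated correlation). Averaged over temperature, 40% light raised miR827 5.85-fold (2.55 ± 0.16, adjusted p = 3.19e-08), miR408 8.76-fold, miR397 4.01-fold and miR399 3.59-fold (adjusted p = 0.000792, 0.000292 and 0.000792; miR399 at 2.50 on the log2 scale without LC replicate 1). It lowered miR395 7.09-fold, miR156 2.49-fold, miR390 2.3-fold and miR168 2.57-fold (adjusted p = 1.14e-06, 2.05e-05, 2.05e-05 and 0.000427), but miR156 and miR168 passed only in the cool regime. The light effect passed for 15 families (4 higher, 11 lower; 4 and 6 with library size only) and 63 miRNAs (32 higher, 31 lower; 41 and 26 with relative-log-expression size factors, 36 and 18 with library size only), 38 of them with a fold of at least 2. With shade the copper list moved up (adjusted p = 8.67e-05, and adjusted p = 0.141 with an estimated correlation). So did the nutrient (adjusted p = 0.000614, and adjusted p = 0.252 with an estimated correlation and 0.986 on family sums) and cold-responsive lists (adjusted p = 0.00537, and adjusted p = 0.306 with an estimated correlation), while of the nutrient families miR827 and miR399 rose and miR395 and miR2111 fell, the latter in the cool regime only. The SPL and AP2 (adjusted p = 0.000699, and adjusted p = 0.202 with an estimated correlation) and small-RNA machinery lists (adjusted p = 1.18e-05, and adjusted p = 0.0962 with an estimated correlation) moved down. So did the MYB-targeting (adjusted p = 0.0239, and adjusted p = 0.259 with an estimated correlation) and leaf and meristem lists (adjusted p = 0.0239, and adjusted p = 0.252 with an estimated correlation). The auxin-signalling list passed in none of the 11 comparisons (adjusted p = 0.307 to 0.977 by fry on its members). On family sums it passed for light (adjusted p = 0.00178) and, with the direction turned, for LC against Control (0.0191), LC against CC (0.0401) and LL against LC (0.00188). The list of regulators of resistance genes held a single miRNA, miR482d-3p_2, too few for fry, which rose 1.53-fold averaged over light (0.62 ± 0.19, adjusted p = 0.0213). The miR482 family sum did not pass in that comparison (0.53 ± 0.23, adjusted p = 0.0791). The reproductive-tissue family of the remaining list was not in the table.

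Against the day 0 leaves, the warm regime under full light (CC) went with lower phosphate and copper families. miR827 went from 203 ± 5.81 to 3.88 ± 0.54 CPM, 51.5-fold lower (-5.69 ± 0.26, adjusted p = 5.9e-10), miR397 was 96.1-fold lower (-6.59 ± 0.57, adjusted p = 6.86e-07) and miR399 62.4-fold lower (-5.96 ± 0.60, adjusted p = 2.69e-06). miR408 was 65.0-fold lower (-6.02 ± 0.98, adjusted p = 0.000197; log2 change -6.77 without CC replicate 1 and -4.87 without Control replicate 2) and miR398 25.1-fold lower (-4.65 ± 0.99, adjusted p = 0.00188; -5.76 without CC replicate 1). miR395 rose 9.64-fold (3.27 ± 0.37, adjusted p = 7.58e-06), miR164 5.07-fold (2.34 ± 0.35, adjusted p = 9.14e-05) and miR403 2.45-fold (1.29 ± 0.17, adjusted p = 3.99e-05). Of 34 families 9 passed (4 higher, 5 lower; 3 and 9 with all reads of the table as library size), and the groups did not overlap in 16 of all 34 (chance 10%). Of the copper list all 3 families and all 7 members fell (3 and 7 adjusted over the list alone), a move that held with an estimated correlation (adjusted p = 5.72e-07, and adjusted p = 0.0048 with an estimated correlation). The nutrient list moved down (2 of 4 families and 7 of 10 members lower, 3 and 8 adjusted over the list alone; adjusted p = 6.93e-05, and adjusted p = 0.11 with an estimated correlation). The leaf and meristem list moved up (adjusted p = 0.0018, and adjusted p = 0.388 with an estimated correlation and 0.059 on family sums), and so did the MYB-targeting list (adjusted p = 0.0475, and adjusted p = 0.62 with an estimated correlation and 0.119 on family sums) with none of its 12 members past the threshold. Among single miRNAs 34 passed, 17 higher and 17 lower (9 and 18 with library size only, 9 and 19 with all reads of the table as library size). The count was 18 without CC replicate 2, 16 without Control replicate 1 and 20 without Control replicate 2.

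In the shaded warm regime (CL) against day 0, miR827 was 14.4-fold lower (-3.84 ± 0.23, adjusted p = 1.92e-08) and miR399 32.1-fold lower (-5.01 ± 0.57, adjusted p = 1.11e-05). miR397 was 23.5-fold lower (-4.56 ± 0.51, adjusted p = 1.11e-05) and miR398 11.4-fold lower (-3.51 ± 0.94, adjusted p = 0.00971). miR408 was 5.97-fold lower (-2.58 ± 0.84, adjusted p = 0.0279). This call was lost without CL replicate 2, CL replicate 3 or Control replicate 2, with a log2 change of -1.42 without the last (adjusted p up to 0.167, 0.00193 to 0.167 over all alternatives). The auxin-receptor regulator miR393 rose 2.67-fold (1.42 ± 0.24, adjusted p = 0.000306), and miR390 was 2.42-fold and miR168 2.4-fold lower (adjusted p = 0.000304 and 0.00971). miR477 stood at 0.459 ± 0.212 CPM against 117 ± 82.4 on day 0 (adjusted p = 0.000172). Of 34 families 13 passed (2 higher, 11 lower; 5 and 10 with library size only), and the groups did not overlap in 16 of all 34 (chance 10%). The copper list moved down, with all 3 families and 6 of 7 members lower (3 and 7 adjusted over the list alone), and held with an estimated correlation (adjusted p = 2.52e-06, and adjusted p = 0.0441 with an estimated correlation). The nutrient list moved down (adjusted p = 7.64e-05, and adjusted p = 0.206 with an estimated correlation; 2 families and 7 members lower, 2 and 7 adjusted over the list alone). So did the small-RNA machinery list (adjusted p = 0.00173, and adjusted p = 0.494 with an estimated correlation and 0.708 on family sums in the other direction), whose families had a median of 0.47 against -1.18 for its members. Among single miRNAs 54 passed, 21 higher and 33 lower (24 and 25 with library size only, 13 and 34 with all reads of the table, 28 and 29 with hairpin reads added), and 35 without CL replicate 1.

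In the cool regime under full light (LC) against day 0, the sulfate regulator miR395 rose 39.2-fold, from 22.0 ± 7.19 to 862 ± 302 CPM (5.29 ± 0.40, adjusted p = 3.32e-07). miR2111 rose 7.47-fold (adjusted p = 3.6e-05) and the SPL regulator miR156 2.59-fold (1.37 ± 0.23, adjusted p = 0.000359). miR168 rose 2.45-fold (adjusted p = 0.00699; log2 change 0.66 without LC replicate 1) and miR159 1.97-fold (adjusted p = 0.00171). miR397 was 18.6-fold lower (-4.22 ± 0.50, adjusted p = 2.79e-05; -5.03 without LC replicate 1). miR408 was 9.07-fold lower (-3.18 ± 0.86, adjusted p = 0.00782; -4.05 without LC replicate 1, -2.02 without Control replicate 2) and miR827 2.96-fold lower (-1.57 ± 0.21, adjusted p = 4.57e-05). miR398 differed by -0.56 ± 0.85 (adjusted p = 0.609), and by -2.78 without LC replicate 1 (adjusted p = 0.00382, 0.00382 to 0.943 over all alternatives). miR399 was 2.52-fold lower (-1.33 ± 0.49, adjusted p = 0.0397; -2.61 without LC replicate 1), a call lost without Control replicate 1 or 3 or LC replicate 2 or 3 (adjusted p up to 0.133, 2.53e-05 to 0.133 over all alternatives). Of 34 families 15 passed (9 higher, 6 lower), and the groups did not overlap in 18 of all 34 (chance 10%). The SPL and AP2 (adjusted p = 0.00132, and adjusted p = 0.203 with an estimated correlation; 2 families higher, 2 adjusted over the list alone) and small-RNA machinery (adjusted p = 0.000333, and adjusted p = 0.139 with an estimated correlation; 2 higher, 2 adjusted over the list alone) lists moved up. Of the former, the miR172 call was lost without LC replicate 3 (adjusted p up to 0.0531, 0.000935 to 0.596 over all alternatives) and with library size only, and by its most abundant member miR172 fell by 0.26 and did not pass. The MYB-targeting (adjusted p = 0.0247, and adjusted p = 0.262 with an estimated correlation) and leaf and meristem lists (adjusted p = 0.0247, and adjusted p = 0.209 with an estimated correlation and 0.129 on family sums) also moved up. The copper list moved down (adjusted p = 1.16e-05, and adjusted p = 0.139 with an estimated correlation; 2 families lower, 2 adjusted over the list alone). The nutrient list moved down over its members (median -1.70; adjusted p = 0.00239, and adjusted p = 0.381 with an estimated correlation and 0.0311 on family sums in the other direction), while its families had a median of 0.78, 2 higher and 2 lower. Among single miRNAs 65 passed, 30 higher and 35 lower (16 and 35 with library size only).

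In the shaded cool regime (LL) against day 0, miR827 rose 3.23-fold, to 654 ± 25.9 CPM (1.69 ± 0.21, adjusted p = 7.89e-05), and miR395 4.35-fold (2.12 ± 0.36, adjusted p = 0.000888). miR156 was 2.33-fold lower (-1.22 ± 0.23, adjusted p = 0.00173), miR390 2.03-fold lower (-1.02 ± 0.21, adjusted p = 0.0023) and miR397 4.73-fold lower (-2.24 ± 0.46, adjusted p = 0.0023). The differences in miR398 (-0.52 ± 0.85, adjusted p = 0.659) and miR408 (-0.37 ± 0.79, adjusted p = 0.715) did not pass. miR399 rose 2.63-fold (1.40 ± 0.49, adjusted p = 0.043). The call was lost whichever of the 6 libraries was left out (adjusted p up to 0.119, 0.00145 to 0.119 over all alternatives). miR164 rose 2.37-fold (1.25 ± 0.34, adjusted p = 0.0133), a call lost without Control replicate 2 or LL replicate 3 (adjusted p up to 0.0557, 0.000188 to 0.0557 over all alternatives). Of 34 families 11 passed (5 higher, 6 lower), and 7 without Control replicate 1, Control replicate 2, LL replicate 2 or LL replicate 3. The groups did not overlap in 15 of all 34 (chance 10%). The nutrient list alone passed of the 8 lists (adjusted p = 0.000139, and adjusted p = 0.243 with an estimated correlation), with 3 of 4 families and 3 of 10 members higher (3 and 3 adjusted over the list alone), though on family sums the SPL and AP2 list passed too (adjusted p = 0.00267). Among single miRNAs 29 passed, 18 higher and 11 lower. The split was 15 and 17 with relative-log-expression size factors, 10 and 10 with library size only, 9 and 24 with all reads of the table and 12 and 16 with hairpin reads added. DESeq2 called 52 and a fit of the LL and Control libraries alone 45, and 19 passed without Control replicate 2, 16 without Control replicate 3 or LL replicate 1 and 14 without LL replicate 2.

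Over the 179 miRNAs tested, which are not independent replicates, the temperature effects in full light and in 40% light, which share no library, had Pearson's r of 0.290 and Spearman's rho of 0.1999. In both, 15 miRNAs were higher, where independent lists would share 5.72, 5 were lower (4.08), and 7 passed in opposite directions. The light effects at the warm and cool regimes had r of 0.0653 and rho of 0.139, with 6 miRNAs higher in both (2.55 for independent lists), 7 lower in both (4.37) and 11 opposite. The 4 comparisons with day 0 share the 3 Control libraries, which gives a correlation with no effect at all. The observed r was 0.690 for CC and CL (simulated with unchanged groups 0.527), 0.439 for CC and LC (0.497), and 0.251 for CC and LL (0.513). It was 0.378 for CL and LC (0.492), 0.191 for CL and LL (0.501) and 0.206 for LC and LL (0.503). The covariance of the log2 changes was 3.40 for CC and CL against a simulated median of 0.464 (95% of simulations 0.194 to 0.95), a difference of 2.93. It was 2.14 for CC and LC (0.479, 0.154 to 0.955, difference 1.66), 1.57 for CL and LC (0.459, 0.19 to 0.908, difference 1.11) and 0.869 for CC and LL (0.474, 0.206 to 0.854, difference 0.395). For CL and LL (0.562 against 0.460, 0.176 to 0.94, difference 0.102) and LC and LL (0.600 against 0.476, 0.18 to 0.847, difference 0.124) it lay inside the simulated range. Over the 34 families all 6 covariances lay above it, at 0.692 for CL and LL (0.0125 to 0.391) and 0.772 for LC and LL (0.0252 to 0.374). For CC and CL, 7 miRNAs were higher and 16 lower in both, where independent lists would share 1.99 and 3.13, with 0 opposite. For the remaining pairs, with the number for independent lists in brackets, 5 (2.85) were higher and 10 (3.32) lower in CC and LC, and 9 (1.71) and 1 (1.04) in CC and LL. They were 5 (3.52) and 15 (6.45) in CL and LC, 6 (2.11) and 5 (2.03) in CL and LL, and 3 (3.02) and 5 (2.15) in LC and LL. Opposite calls numbered 3 in CC and LC, 3 in CC and LL, 11 in CL and LC, 3 in CL and LL and 8 in LC and LL. The 3 Control libraries cannot be split into parts of at least 2, so part of the excess in the pairs above the simulated range may come from the shared controls.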

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

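The tests of explanations for LC replicate 1, for member names and for animal precursor reads were chosen after those results were seen, while the counts over other splits of the libraries were planned. For 11 families the effect of the cool regime differed between 40% and full light by the interaction test, on the log2 scale. It was higher in 40% light for miR164 (4.02), miR169 (5.24) and miR827 (1.42), and lower for miR156 (-2.56), miR2111 (-2.85), miR157 (-1.44), miR168 (-1.84), miR858 (-1.73), miR393 (-0.98) and miR171 (-0.92). For miR477 the fitted 10.20 rests on 4 reads in the CL libraries and is no measure of size. That of miR169 rests on 27 reads in CL and 59 in LC, 46 of them in LC replicate 1, so its size is uncertain. Of 100 splits of the 12 day 14 libraries, 1, the real one, gave as many calls. The real split gave 62 miRNAs and 11 families, the highest other 29 and 7. Each other split mixed all day 14 groups and so also broke the temperature and light effects. The counts therefore exceed those of groups with no difference at all. They cannot tell whether chance gave the interaction calls.

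Signals outside the miRNA comparisons lay above the Control libraries. Reads matching the animal precursor mir-184 stood at 10.6 to 47.3 RPM (reads scaled to the total of the table) in the LC libraries, 4.64 to 8.88 in CC and 0.973 to 3.82 in Control. Predicted siRNAs were counted if all 3 libraries of a group held at least 100 reads and at least 2 times the RPM of the highest Control library. These numbered 1 in CC, 29 in CL, 19 in LC and 15 in LL and were not tested further. Of the 7972 listed, those with fewer reads were not eligible, so the numbers give no share of the list. Groups of 3 are too small for the test of a sample far from the others, so none was run.

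Reads matching animal miRNA precursors occurred in these leaf libraries. Loose matches of plant fragments present in every library are argued against for families known from protostomes (insects and their relatives), with or without vertebrates, of which CL and LL held 1.18 RPM on average against 30.7 in CC (ratio 0.0384; 0.103 against 6.05 for those known only from protostomes). They are also argued against for families known only from vertebrates in LC (1.59 against 70.5, ratio 0.0225, or 0.0840 without LC replicate 1). For the low level of vertebrate families in CC (1.45 RPM, ratio 1.10) such matches stay open, as do plant RNAs that change with light, which were not tested, and arthropods on the leaves can neither be excluded nor shown, since with group means removed 3 families known only from protostomes had a median Spearman's rho of 0.333 over the 9 Control, CC and LC libraries (p = 0.0912 by 10000 permutations within groups). Reads carried over from vertebrate libraries may be a source, since the profile of vertebrate families in Control replicate 3 correlated with that in LC replicate 1 at r = 0.977, the highest of 10 pairs of 5 libraries, 4 of them within a group.

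LC replicate 1 stood apart from LC replicates 2 and 3 in the copper families miR397 and miR398 and the phosphate family miR399, but not in miR827, and for miR408 all 3 libraries differed. A mislabelled library would lack the LC pattern, but of the 52 miRNAs in which LC replicates 2 and 3 lay beyond all libraries of the other groups, LC replicate 1 did so too in 37 (71.2%). RNA of Control or LL leaves mixed in would need shares of 1.54 to 2.87 of the library for miR398, which is above the possible 1. Scaling set by an abundant miRNA is argued against by a difference of 8.48-fold in RPM of the whole table. A difference between the leaves or plants of the LC group stays open, untested because no label tells them apart, and so does one in handling, since vertebrate precursor reads also stood at 173.7 RPM in this library against 22.5 and 15.4.

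Within some families, reads sat under different member names in different libraries, as for miR395a_5 and miR395b_3 (within-group r -0.959) and miR162-3p and miR162a-3p (-0.95). If near-identical names shared reads as a rule, members of a family would fall as others rise. Their median within-group correlation was instead 0.249 over 242 pairs, against -0.00717 over 5218 pairs from different families. A median over all pairs cannot tell whether a few of them share reads. Sharing in many pairs would leave an excess of pairs with r under -0.7. These made up 2.48% (6 of 242) within families and 2.84% (148 of 5218) between them (permutation p = 0.68). Pairs across families are no clean background, however. CC replicates 1 and 3, LC replicate 2 and LL replicate 3, which the third principal component set apart, held mainly miR162a-3p and miR395a_5. Control replicate 1 held mainly miR162-3p and miR395a_5, and the remaining libraries miR162-3p and miR395b_3. A switch in the same libraries can also lower the correlation of pairs across families. The comparison therefore cannot decide whether names share reads, in many pairs or in a handful. Members that vary between leaf samples on their own or together stay open for families as a whole, with the variance of a family's sum at a median of 1.04 times the summed variances of its members (95% bootstrap interval 1.00 to 1.16). The ratio ranged from 0.192 to 1.79 and lay under 1 in 6 of 25 families. For the 2 pairs noted, the reads argue against members that vary on their own or together. In each library 1 of miR162-3p and miR162a-3p held at least 6709 reads and the other at most 132. For miR395a_5 and miR395b_3 these bounds were 43 and 13. Reads listed under either name would give such a switch. The sequences are not in the table, so sharing of reads was not tested directly.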

How the results depend on the processing

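The uses of all reads of the table as library size, of hairpin reads added or left out and of miRNAs without the predicted ones, and the leave-outs, DESeq2 and library-size fits of families, were chosen after seeing the data, and the other alternatives were planned. For the family results named, 2009 of 2285 comparisons with an alternative kept direction and side of the threshold, 246 lost the call, 16 gained it and 14 changed direction. For the single miRNAs named, 2468 of 2674 kept both and 206 lost the call. They had been picked among called miRNAs, mostly for groups that did not overlap and the largest changes, which favours a kept call. These numbers therefore do not describe all calls of single miRNAs. The cause of lost calls was not tested. With predicted miRNAs left out, 21, 24, 23 and 18 miRNAs were called for CC, CL, LC and LL against Control, 32 for LC against CC, 29 for LL against CL, 13 for CL against CC, 45 for LL against LC, 24 for the interaction, 26 for temperature and 28 for light. For LL against Control DESeq2 called 52 and a fit of the groups compared 45. That fit called 43 for LC against CC and 20 for CL against CC, library size only called 19 for the latter, and a fold of at least 2 left 38 for light. With the most abundant member per family, 7 families passed in the interaction, and miR172 in LC against Control went to -0.26. Leaving out single libraries gave 16 to 31 miRNAs for CC against Control, 35 to 45 for CL, 14 to 27 for LL, 27 to 40 for LL against CL and 11 to 35 for CL against CC. It gave 7 to 8 families for LL against Control and 4 to 12 for LL against CL. The uncalled miR408 in LL against Control ranged from -0.72 without Control replicate 1 to 0.79 without Control replicate 2, with 0.01 without LL replicate 3. The uncalled miR398 in LL against LC was 2.35 without LC replicate 1, -0.41 without LC replicate 2, -0.43 without LC replicate 3 and -0.17 without LL replicate 1. The uncalled miR156 in CL against CC was 0.0212 with relative-log-expression size factors or DESeq2, 0.0220 with mature entries only, 0.20 with library size only, 0.07 without CC replicate 3, 0.11 without CL replicate 1 and -0.14 without CL replicate 3. The uncalled miR2111 was -0.0133 without CC replicate 2 and 0.32 without CC replicate 1 in CL against CC, and -0.0609 with library size only in LL against CL.

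Camera with an estimated correlation asks whether a list moved more than the other miRNAs, which is another question than that of fry. Of the 45 list results that passed by fry, 2 also passed by camera (copper in CC and CL against Control), 42 did not and 1 turned, and the other 43 of 88 passed by neither. The adjusted p of camera against Control were 0.620 (MYB), 0.388 (leaf) and 0.110 (nutrient) for CC, 0.206 (nutrient) and 0.494 (machinery) for CL, 0.203 (SPL), 0.262 (MYB), 0.139 (copper and machinery), 0.209 (leaf) and 0.381 (nutrient) for LC, and 0.243 (nutrient) for LL. They were 0.403 (SPL, copper and machinery) and 0.434 (nutrient) for LC against CC, and 0.0506 (copper and nutrient), 0.875 (leaf), 0.672 (machinery) and 0.797 (cold) for LL against CL. For CL against CC they were 0.602 (MYB), 0.135 (copper and machinery) and 0.408 (leaf), and for LL against LC 0.169 (SPL and machinery), 0.220 (copper and nutrient) and 0.577 (cold). For the interaction they were 0.570 (SPL) and 0.932 (nutrient, and leaf in the other direction), for temperature 0.102 (copper), 0.108 (nutrient) and 0.313 (machinery), and for light 0.202 (SPL), 0.259 (MYB), 0.141 (copper), 0.252 (leaf and nutrient), 0.0962 (machinery) and 0.306 (cold). With the replicate number as a block, fry kept 39 of the 45, lost MYB in CC (0.0849) and LC against Control (0.0501), CL against CC (0.0901) and light (0.0841), and leaf in LL against CL (0.178) and the interaction (0.1004). It gained SPL in LL against Control (0.0251), LL against CL (0.0496) and temperature (0.0373). On family sums fry kept 32 of the 45. Against Control it lost MYB (0.119) and leaf (0.0590) and gained machinery and cold (0.0105) in CC, turned machinery (0.708) and gained cold (0.00260) in CL, turned auxin (0.0191) and nutrient (0.0311), lost leaf (0.129) and gained cold (0.00181) in LC, and gained SPL in LL (0.00267). It gained MYB (0.0317) and turned auxin (0.0401) in LC against CC, and gained SPL (0.00502) and lost leaf (0.504) and machinery (0.365) in LL against CL. It lost MYB (0.160), leaf and machinery (0.0604) in CL against CC, gained MYB (0.00156) and turned auxin (0.00188) in LL against LC, lost leaf (0.260) and turned nutrient (0.792) in the interaction, gained cold in temperature (0.0449), and gained auxin (0.00178) and lost nutrient (0.986) in light.

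Whether the replicate numbers pair the libraries is not known, and no pairing was detected. Within-group residuals of the same number had a median r of 0.013 (30 pairs, -0.383 to 0.45). Those of different numbers had 0.00807 (60 pairs, -0.49 to 0.524). A check by number cannot show other groupings of libraries. One such was that of CC replicates 1 and 3, LC replicate 2 and LL replicate 3 on the third principal component. Counts of calls with the block stayed within 1.5 times those without it, as for 75 miRNAs and 18 families in LC against CC. A pseudocount and a filter on low values of normalized data were not run, since counts were deposited, and counting identical miRNAs once moved nothing, since 0 tested miRNAs were identical. In simulated data, 13.2% of 2-fold changes of miRNAs were recovered, and whether depth, number of libraries or their spread limits this was not tested.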

Other observations

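The tests of the phosphate and copper hypotheses were chosen after the levels had been seen, and the splits of the libraries were planned. Among predicted miRNAs, novel_mir29 and novel_mir61 set the LC libraries apart. novel_mir29 stood at 1952 ± 726 CPM in LC, against 124 ± 139 in CC, 69.6 ± 47.7 on day 0 and 44.7 ± 30.9 in LL. Its call in LL against LC (-5.45 ± 1.16, adjusted p = 0.0023) held under each alternative, and that in LC against CC (3.97 ± 1.08, adjusted p = 0.0101) was lost when only those groups were fitted. novel_mir61 stood at 17.0 ± 8.63 CPM in LC and 197 ± 43.6 in LL (3.53 ± 0.45, adjusted p = 7.52e-05), against 214 ± 55.2 in CC and 209.9 ± 24.5 on day 0. In CL it was 2.35-fold below CC, a difference that did not pass (-1.23 ± 0.42, adjusted p = 0.0616). miR858, a regulator of MYB factors of the flavonoid pathway, stood at 107930.0 ± 35533 CPM on day 0, 84183 ± 13889 in CC, 158010.0 ± 89313 in CL, 121290.0 ± 9058 in LC and 68721 ± 21421 in LL.

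Because miR399 and miR827 both answer to phosphate in other plants, a shared signal of phosphate status may move them together from library to library. With group means removed, their correlation over 15 libraries was r = 0.189 (permutation p = 0.962, adjusted p = 0.962) and Spearman's rho -0.107 (permutation p = 0.793, adjusted p = 0.797), with r = 0.317 without LC replicates 1 and 2 and -0.0772 on RPM of the whole table. A relation was not detected, and its absence is not shown either. A shared copper signal may likewise move miR397, miR398 and miR408. The smallest of their 3 correlations was r = 0.208, for miR397 and miR408 (permutation p = 0.625, adjusted p = 0.833; Spearman's rho 0.0964, permutation p = 0.797, adjusted p = 0.797; r = -0.293 without LC replicate 1 and CC replicate 1 and -0.015 on RPM). For miR397 and miR398 r was 0.852 (permutation p = 0.0179, adjusted p = 0.0716; Spearman's rho 0.689, permutation p = 0.0473, adjusted p = 0.189; r = 0.655 without the same 2 libraries and 0.788 on RPM). For miR398 and miR408 r was 0.521 (permutation p = 0.243, adjusted p = 0.486; Spearman's rho 0.439, permutation p = 0.187, adjusted p = 0.374; r = 0.205 without those 2 and 0.447 on RPM). None of the 4 relations passed after adjustment, and the tests were two-sided with 1e+05 permutations.

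For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. Each other split also mixed the 2 groups compared, so a difference between them widened the spread and left few calls. Low counts in those splits are therefore no measure of chance. The real number of called miRNAs and the highest of the other splits were 34 and 1 for CC against Control, 54 and 0 for CL, 65 and 0 for LC and 29 and 0 for LL. They were 76 and 0 for LC against CC, 48 and 0 for LL against CL, 31 and 0 for CL against CC and 91 and 0 for LL against LC. For families they were 9 and 0, 13 and 0, 15 and 1 and 11 and 0 against Control, in the same order, and 20 and 1, 12 and 0, 12 and 0 and 15 and 0 for the others. For the averages, 1 of 100 splits, the real one, gave as many calls. These splits mixed all day 14 groups. Chance is therefore argued against for differences between the groups as a whole, not for temperature or light alone. The real and highest other values were 69 and 25 miRNAs and 13 and 7 families for temperature, and 63 and 23 miRNAs and 15 and 5 families for light.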
